A study of Nicotiana tabacum with 4 samples.

How the data were processed

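RNA from 4 samples of tobacco leaf discs was analysed: control (empty vector) and WIPK/SIPK-suppressed plants, each at 9 h and 24 h after wounding and then 4.5 h in cycloheximide. Per the labels' protocols, plants were 6 to 7 weeks old and raised on vermiculite with days of 16 h light at 25 °C, total RNA was extracted with Trizol, and 100 ng was labelled with Cy3 by a low-input amplification kit. The labels describe the series as a single experiment. Each sample was hybridised to 1 array of a 1-colour Agilent tobacco design, and all 4 arrays lay on 1 slide scanned on 1 day, so there was no batch of slide or day to fit.

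The deposited scanner files hold spot intensity on a linear scale. Per the file headers they were made with Agilent Feature Extraction 10.7.3.1, which subtracted the background, removed spatial and multiplicative trends, put a surrogate value on spots not above background (25.1% to 31.2% of spots per array) and gave each spot an error from its error model. The processed intensity was the unit analysed, with the mean spot and median local background intensities used in an alternative. Flags for spots well above background, saturated or outlying came from the same files, per the file headers. The deposited series value table was set against the scanner files: in each column the values equalled the processed intensity divided by the array's median over its non-control spots, within 0.005, with a column median of 1. Its scale was therefore linear, and it was used as an alternative.

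The processed signal was taken to log2 and the array's 75th percentile over non-control spots (521.1 to 613.3) was subtracted. Spots of a probe were averaged. Probes with an outlying spot (0 to 6 spots per array) were left out of comparisons with that array, but were kept in the additive fit below. The 11 probes spotted more than once gave 40 sets of repeated spots, which differed by a median of 0.14 and at the 95th percentile by 0.31 on the log2 scale. The median spot error was 10.1% of the signal. Probes were tested in a comparison when at least 1 of its 2 arrays had them well above background. On an array where a probe was not well above background, the higher of its own value and the lowest value well above background on that array (log2 of -4.83, -3.64, -4.13 and -4.83 for control 9 h, control 24 h, suppressed 9 h and suppressed 24 h) was used. Where the other array was the higher, the fold is a lower bound, written as at least. Where that floor lay above the other array's value, the floor set the order of the arrays. This held for 588 of the 24825 probes tested between genotypes at 9 h and 1873 of 24634 at 24 h, and for 1775 of 24162 between times in control and 698 of 24818 in suppressed leaves. None of these values could be called, but they entered list medians. For the difference of differences the highest of these floors served all arrays. That choice was made after the data were seen, because each array's own floor had given 359 probes higher and 1722 lower, an imbalance that followed the floors. A probe was called at a log2 difference of 1 with the brighter array well above background. With 1 array per group no p-value between arrays was computed. An additive fit of genotype and time (limma 3.58.1 in R 4.3.3, eBayes with trend, Benjamini-Hochberg adjusted p of 0.05) used 1 residual degree of freedom per probe over 23951 probes. The values it used had no floor. The fit was tested on simulated data of 23951 probes: 56.7% of probes changed by a log2 of 1, 92.5% of those changed by 2 and 97.0% of those changed by 4 were recovered, with 11 false calls among 175. Only 67, 67 and 66 probes were changed by these sizes. The simulated noise was independent, with a spread smoothed over signal and no error shared within a genotype. These rates therefore need not hold for the real calls.

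Gene names are those of the array's description column, with the identifiers of the array design, since 0 of the probe accessions matched the gene table given for assembly ASM71507v2. Of 43759 probes, which carry 40425 identifiers, 16014 are described as unknown and 5934 name a gene product. No genome coordinates were used. Where an identifier had several probes, the probe with the highest mean signal stands for it. Over 1893 identifiers with a pair of probes, the genotype differences at 9 h had an r of 0.97, and 316 pairs were past a log2 of 1 with the same sign and 0 with opposite signs.

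Before the data were examined, 24 gene lists were fixed as search words over the descriptions. A list's median was set against the medians of 10000 random lists of the same size matched on mean signal in 20 bins, and a list outside the central 95% was counted. Lists with fewer than 5 members got no percentile. These percentiles describe the arrays and are no test between genotypes. On lists of 20 probes drawn at random in the 9 h genotype comparison over 22313 probes, 4.0% of 200 lists fell outside, and 85.0% and 100% did after 0.5 and 1 were added to their medians. The genes named were also chosen by a rule fixed beforehand: the target kinases, the 8 highest and 8 lowest descriptions called the same way at both times, 6 each way at each time, 8 each way for the control's time difference and 4 for that of suppressed leaves, 5 each way for the difference of differences, and up to 4 members of each list. A probe whose description rests on a partial match to a bacterial protein met the rule among those lower at 24 h and was left out after its value was seen. The intervals of list medians are bootstrap intervals from 2000 draws.

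The alternatives fixed beforehand were normexp background correction with an offset of 50, quantile and cyclic loess normalization, median centring, a filter that asked for every array compared to be well above background, no filter, the deposited series value table, a call that also asked for a difference beyond the 95% range of the spot error, eBayes without trend, and lists with all matching probes. A slide block was not fitted, with all arrays on 1 slide. Random lists drawn from named probes only, lists without the probes ordered by the floor, each array's own floor for the difference of differences, and a size limit on the additive fit were added after seeing the data, as were 8 further gene lists. Tables were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.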

Results

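Gene expression was measured in leaves of tobacco (Nicotiana tabacum) transformed with an empty vector, called control here, and in leaves of plants in which the mitogen-activated protein kinases WIPK and SIPK were both suppressed. WIPK is the wound-induced protein kinase and SIPK the salicylic acid-induced protein kinase of tobacco, and both are known to be activated by wounding. Leaf discs of 10 mm diameter were floated on water for 9 h or 24 h and then kept for 4.5 h with cycloheximide, an inhibitor of cytosolic protein synthesis. The centre of each disc, 5.5 mm across, was used for RNA, so that the tissue at the wounded edge was left out. The series asked which genes the kinases regulate in wounded leaves. Each of the 4 combinations of genotype and time was hybridised to 1 array, so there were no replicates, and the number of arrays limits the precision of every value below. Between 48.4% and 55.7% of the non-control spots were well above background on each array, and 0 spots were saturated. Of the 43759 probes, 25697 were well above background on at least 1 array and 20524 on all 4. A probe was called higher or lower when the 2 arrays compared differed by at least 2-fold (a log2 difference of 1), and these calls describe the arrays and carry no p-value. The error given after a ± is the spot error of the log2 difference from the scanner's error model. It was near 0.20 for bright probes, is given below for some of the values where it was larger, and holds no variation between plants.

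The transcripts of both targeted kinases were lower on the suppressed arrays at both times. The WIPK probe (D61377) was 25.0-fold lower at 9 h (log2 difference -4.64) and 17.7-fold lower at 24 h (-4.14). The SIPK probe (U94192) was 34.8-fold lower at 9 h (-5.12) and 21.0-fold lower at 24 h (-4.39). Both probes stayed well above background on the suppressed arrays, with processed signals of 1730 and 2281 for WIPK against 42414 and 37532 on the control arrays. Suppression was by RNA interference, per the labels. Whether the probes lie inside the sequence used for it is not given, and RNA of the construct would add to the remaining signal and make these folds too small. In the control, the 24 h array differed from the 9 h array by 0.03 for WIPK and by -0.25 for SIPK. Other members of the family were also lower: Ntf4-1 (DQ229077), a kinase closely related to SIPK, had differences of -4.00 at 9 h and -3.16 at 24 h, and a probe described as MAP kinase homolog (TA17412_4097) had -1.35 and -1.65. A further probe described as salicylic acid-activated MAP kinase (TA15044_4097) was not well above background in suppressed leaves at 9 h and was 10.6-fold lower at 24 h. The list of MAP kinase cascade genes also held the SIPK probe, Ntf4-1 and TA15044_4097. In this list, 5 of 17 members were lower and 3 higher at 9 h, and 7 of 16 were lower and 4 higher at 24 h. Its median of -0.52 at 9 h lay at percentile 0.22 of 10000 random lists matched on signal, and its median of -0.39 at 24 h at percentile 6.52. Without 2 members whose order was set by the background floor, the 24 h median was -0.88, outside the random range. These medians include the suppressed target and close relatives of it, and the list was not examined without them. Its place among the random lists is therefore no evidence on the rest of the cascade. The members called higher were all described as MAP kinase kinases (AF165186, 1.18 and 1.15, BP530009, 1.27 and 1.77, EB424604, 1.30 and 1.76, and at 24 h BP132972, 1.46 ± 0.24).

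**Figure D1:**
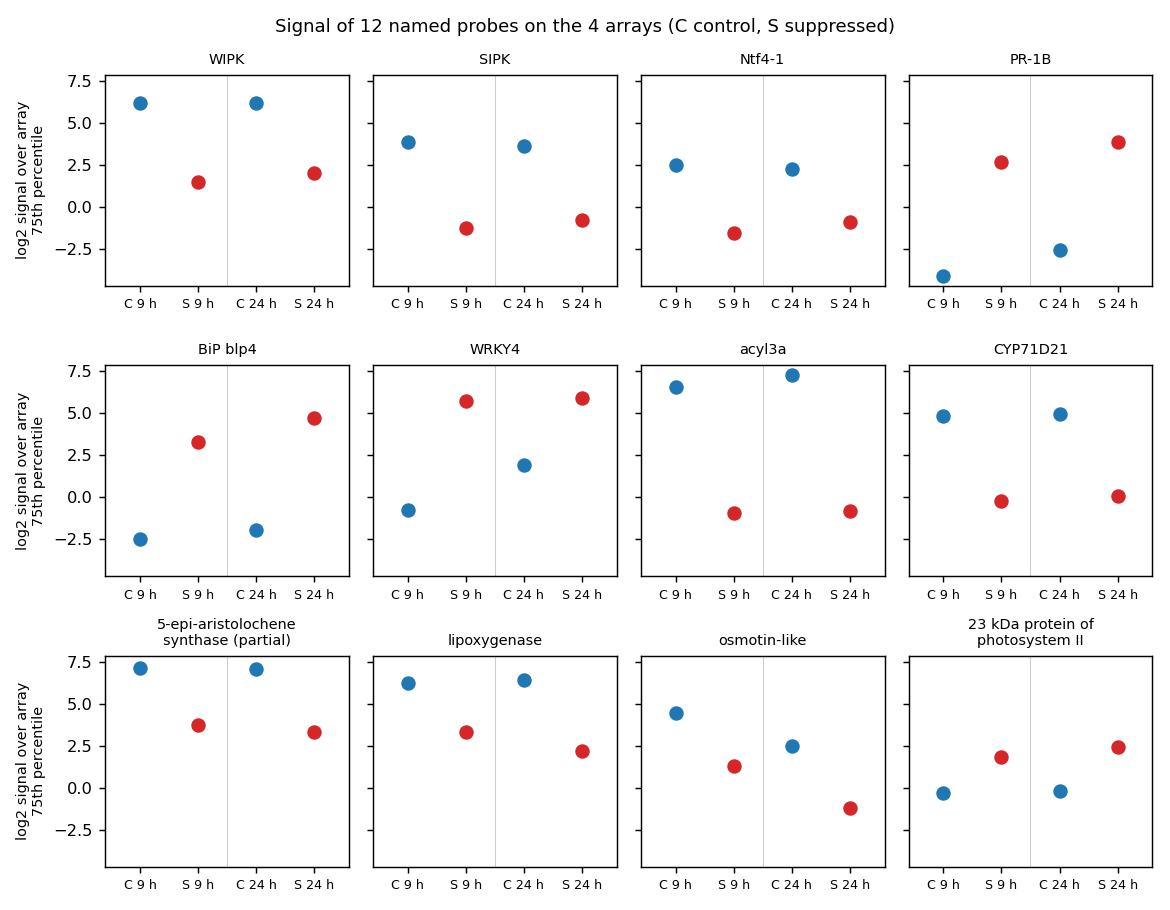
Normalised log2 signal of 12 named probes (panels) on the 4 arrays, in the order control and suppressed at 9 h, then control and suppressed at 24 h (C, blue, control; S, red, suppressed). Each point is 1 array and filled points were well above background. Signals are to be compared within a panel: WIPK and SIPK lie at least 4.14 log2 units lower in suppressed leaves at each time, while PR-1B and the luminal binding protein blp4 lie at least 5.73 higher.

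Suppressed and control leaves were then compared at each time, which asks which transcripts differ between the genotypes. All 4 samples were wounded and then given cycloheximide. Whether a difference was present before wounding, or depends on cycloheximide, therefore cannot be told. Among the probes whose description names a gene product, 5934 of 43759, those lowest in suppressed leaves at both times included cytochromes P450 and acyltransferase-like proteins. A cytochrome P450 hydroxylase (TA15860_4097) had log2 differences of -9.65 ± 0.28 at 9 h and -10.87 ± 0.26 at 24 h, and CYP71AU1 (DQ350357), another P450, had -7.62 ± 0.25 and -7.92 ± 0.26. An acyltransferase-like transcript (acyl3a, AB176527) was 178-fold lower at 9 h and 271-fold lower at 24 h, and a second probe of that description (TA16222_4097) 188-fold and 310-fold. Further down came the peroxidase NtPOX1 (AB178953, -5.29 and -6.12), CYP71D49v1 (DQ350340, -5.44 and -8.51) and CYP71D5v2 (EG649696, -5.41 and -6.50). A sulfate adenylyltransferase probe (AJ344597) was not well above background on the suppressed arrays and was at least 66.9-fold lower at 9 h and at least 87.4-fold lower at 24 h.

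The named probes highest in suppressed leaves at both times included an LRR protein, a receptor-like kinase, PR-1B and luminal binding proteins of the endoplasmic reticulum. An LRR protein (TA13001_4097) was 239-fold higher at 9 h and at least 297-fold higher at 24 h, and a receptor-like protein kinase (EG650123) was at least 231-fold and at least 215-fold higher. The probe of pathogenesis-related protein 1B (EH624149), known as a marker of salicylic acid responses, had log2 differences of 6.76 ± 0.29 at 9 h and 6.40 ± 0.25 at 24 h. Its processed signals on the control arrays were low, 34.7 at 9 h and 88.5 at 24 h, against 3830 and 8026 on the suppressed arrays. PAR-1c (X83852) had 6.73 ± 0.28 and 4.88, and a cysteine proteinase-like protein (TA21757_4097) had 6.26 and 6.60. The luminal binding protein blp4 (X60057, BiP, a chaperone that folds secretory proteins) was 53.0-fold higher at 9 h and 102-fold higher at 24 h. Luminal-binding protein 8 (TA14838_4097) was 28.8-fold and 74.0-fold higher, and a homolog of the Lon protease (BP132749) 29.4-fold and 31.9-fold.

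At 9 h, 2747 of 24825 probes were higher and 2250 lower in suppressed leaves, 20.1% in all. Which direction had more calls depended on the scaling, with 2190 higher and 2379 lower after quantile normalization, 1978 and 2593 after cyclic loess, 1654 and 3396 after median centring and 1012 and 4480 with normexp. WRKY4 (AF193771), a transcription factor of the WRKY family, was 88.0-fold higher at 9 h and 16.2-fold higher at 24 h, and a probe described as DNA-binding protein 4 (TA22119_4097) had differences of 7.14 and 4.83. A probe described as WRKY transcription factor 6 (CV016080) had 6.79 ± 0.24 and 4.24, HSR201 (X95343), a gene known from the hypersensitive response, 5.15 and 4.28, and the glucosyltransferase NTGT1a (AB052557) 4.05 ± 0.22 and 3.07. The elicitor-inducible receptor-like protein EILP (AB029327) was at least 17.1-fold higher at 9 h. Lower at 9 h were divinyl ether synthase (AF070976, -5.12), an enzyme of the oxylipin pathway, the elicitor-inducible P450 CYP71D21 (AF368377, -5.04), CYP71D48v2 (DQ350337, -5.00), CYP71D47v1 (DQ350335, -4.81), CYP71D48v1 (DQ350338, -4.69) and aristolochene synthase (EH619297, -4.70).

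At 24 h, 2385 of 24634 probes were higher and 2909 lower in suppressed leaves, 21.5% in all. Probes of the luminal binding proteins filled much of the upper end, with differences of 5.41 for luminal-binding protein 3 (TA19868_4097), 5.27 for blp1 (X60060), 4.93 for luminal-binding protein 5 (TA15516_4097) and 4.58 for blp2 (X60059). A hypersensitive-induced reaction protein (EH621663) had 4.42 and a Drm3-like protein (TA17464_4097) 3.92 ± 0.28. At the lower end stood a suberization-associated anionic peroxidase (CV019292, -7.44 ± 0.31), a pectin methylesterase inhibitor (TA14391_4097, -6.06 ± 0.24), a precursor of phytosulfokine, a peptide hormone (TA16652_4097, -5.24), and sucrose synthase (EH623011, -5.21). The pathogenesis-related protein STH-2 (TA13712_4097) was at least 49.0-fold lower.

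The calls at both times overlapped. Of 23767 probes tested at each time, 1597 were higher and 1856 lower at both, where independent lists of these sizes would share 254.8 and 264.7, and 33 went in opposite directions against 526.3 for independent lists. Across the 20524 probes above background on all arrays, which are not independent replicates, the differences at 9 h and 24 h had a Pearson r of 0.89 and a Spearman rho of 0.84, with no array shared between them. In an additive limma fit of genotype and time, 4525 of 23951 probes had higher and 4879 had lower signal in suppressed leaves at a Benjamini-Hochberg adjusted p of 0.05, among them all 3453 probes called the same way at both times. The fit had 1 residual degree of freedom per probe, and eBayes added 4.9 prior degrees of freedom from the other probes. That p therefore sets the mean genotype difference against a variance drawn mostly from other probes. It does not measure the spread between plants, and a small p does not show that the difference was alike at both times. For example, CYP71D49v1 (DQ350340) had -5.44 at 9 h and -8.51 at 24 h (limma adjusted p = 0.0007). The fitted differences were -4.39 for WIPK (limma adjusted p = 6.1e-05) and -4.75 for SIPK (limma adjusted p = 7.7e-05). With normexp background correction in place of the scanner's own, 1724 probes were called the same way at both times and the fit called 3802.

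**Figure D2:**
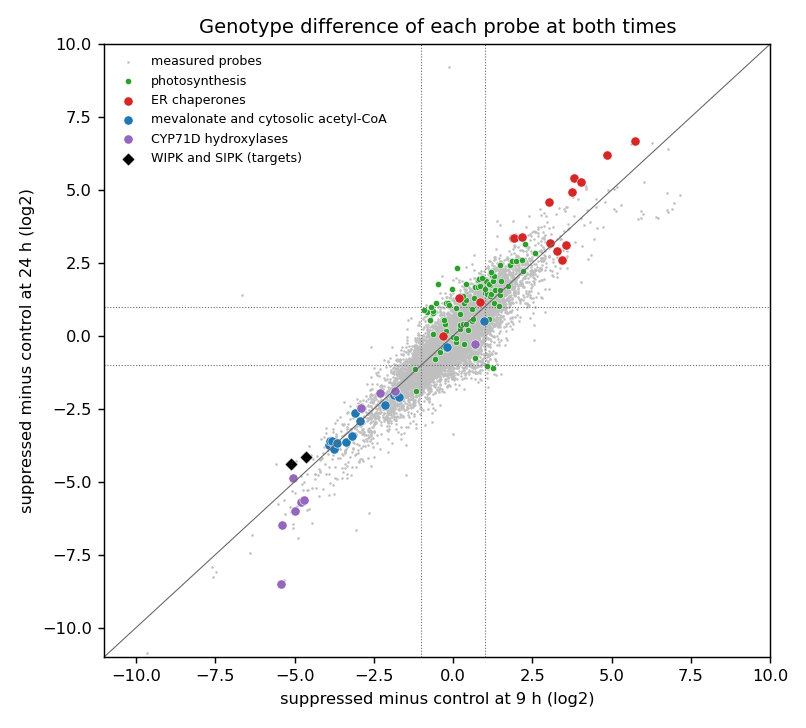
Log2 difference of suppressed minus control at 9 h (horizontal axis) and at 24 h (vertical axis), for each probe measured above background in both comparisons (grey points), with the members of 5 gene lists in colour, bounds included; dotted lines mark a log2 difference of 1 in size and the solid line equal differences. Across the 20524 probes above background on all arrays, Pearson's r was 0.89; most ER chaperones lie in the upper right and most mevalonate pathway, CYP71D and all target kinase probes in the lower left.

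Among the lists fixed before the data were examined, those of defence metabolism were lower in suppressed leaves. All 3 members of the sesquiterpene phytoalexin list were lower at both times, with medians of -4.02 at 9 h and -4.72 at 24 h: aristolochene synthase above, vetispiradiene synthase (TA13185_4097, -4.02 and -4.72) and 5-epi-aristolochene synthase (AF272244, -3.35 and -3.75), the enzyme class that starts the synthesis of the phytoalexin capsidiol. Of the nicotine and polyamine list, 9 of 16 members were lower at 9 h and 10 of 17 at 24 h, with 0 higher at either time (medians -2.03 and -1.66, both at percentile 0). With no filter on background its 9 h median was -0.05 over 26 members, inside the random range (percentile 5.41). The 9 members lower at 9 h were all probes of quinolinate phosphoribosyltransferase (such as AB038494, -3.80 and -3.21), ornithine decarboxylase (Y10472, -3.15 and -2.73) or arginine decarboxylase (TA12478_4097, -2.50 and -3.28), which supply the rings of nicotine and the polyamines. The percentile counts such copies as separate members. Another quinolinate phosphoribosyltransferase probe (EB433697, 0.60 ± 0.22 and 0.06 ± 0.22) and the probes of spermidine synthase, spermine synthase and N-carbamoylputrescine amidase were not called at either time. Nor was N-methylputrescine oxidase NtMPO2 (AB289457, 0.23 ± 0.33 and -0.26 ± 0.34), whose signals were low. The further member lower at 24 h was putrescine N-methyltransferase (D28506, at least 2.69-fold), well above background only in control at 24 h, with a signal of 49.4. In the phenylpropanoid list, 17 of 40 members were lower and 0 higher at 9 h (median -0.96, percentile 0) and 10 of 36 were lower and 2 higher at 24 h (median -0.57, percentile 0.05). Hydroxycinnamoyl CoA quinate transferase (AJ582651, -2.26 and -2.41; EB432226, -2.58 and -3.45), which makes chlorogenic acid, and a hydroxycinnamoyl transferase (TA12691_4097, -2.70 ± 0.32 and -2.40 ± 0.25) were among them.

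The hormone lists differed from each other. The ethylene list had 7 lower and 3 higher of 37 members at 9 h and 8 lower and 1 higher of 37 at 24 h (medians -0.59 and -0.60, percentiles 0 and 0.01). ACC synthase (BJ999148, -2.53 and -3.12) and an ACC oxidase (EB444740, -2.51 and -2.20), the enzymes of ethylene synthesis, were lower, while other copies, picked out after their values were seen, were not: the ACC oxidases X83229 (1.68 and 0.94) and TA12625_4097 (1.76 and 1.17) were higher at 9 h, and the ACC synthase AJ005002 had 0.06 and -0.23. Also lower was the factor NtERF5 (NP8635342, -2.04 and -2.22), while an ethylene receptor homolog (BP526215) had -1.59 ± 0.29 at 9 h and was at least 4.77-fold lower at 24 h. Of 13 jasmonate biosynthesis members, 6 were lower and 3 higher at each time (medians -0.40 and -0.61, percentiles 5.40 and 1.57), and with normexp the 24 h median was inside the random range (-0.23, percentile 25.3). A lipoxygenase (X84040, -2.94 and -4.22), allene oxide cyclase (AJ308487, -2.60 and -1.99; DW004249, -2.56 and -1.64) and 12-oxophytodienoate reductase 3 (TA15530_4097, -2.11 and -2.25) were lower. The 3 higher members, picked out after their values were seen, were also described as lipoxygenase: EB430793 (3.01 and 2.75), EB681141 (2.84 and 2.58) and TA16575_4097 (2.60 ± 0.25 and 2.25 ± 0.26). The lipoxygenases BP533230 (-0.13 and 0.39) and AJ344609 (0.02 and 0.44) were not called. The descriptions of the lipoxygenase probes, X84040 among them, do not say whether the enzymes act in jasmonate synthesis. In the jasmonate response list, 3 of 15 members were lower and 0 higher at 9 h, and 3 lower and 2 higher at 24 h (medians -0.29 and 0.01, percentiles 5.78 and 51.9, with a mean of -0.28 at 24 h). NtJAZ1 (AB433896) had -1.58 and -2.03, and NtJAZ2 (AB433897) -0.93 and -0.49. The salicylate list went the other way, with 2 of 8 members higher at 9 h, 3 of 9 at 24 h and 0 lower (medians 0.45 and 0.80, percentiles 95.4 and 99.9). EDS1-like protein (TA21618_4097, 3.45 and 3.09) and EDS1 (DW003049, 2.56 and 1.83), regulators of salicylic acid responses, were higher at both times, and NPR1 (DQ837218), a receptor for salicylic acid, had 0.67 and 1.13. The auxin list had 3 of 20 members higher at 9 h and 4 of 18 at 24 h, with 0 lower (medians 0.21 and 0.28, percentiles 83.4 and 92.7). The auxin-induced protein PCNT115 (BP192557) had 2.20 and 3.22.

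Pathogenesis-related (PR) genes and WRKY factors moved in both directions. Of 39 PR members at 9 h, 16 were lower and 7 higher, and of 41 at 24 h, 17 were lower and 5 higher (medians -0.40 and -0.47, percentiles 0.37 and 0.70). Lower were an osmotin-like protein (TA12782_4097, -3.12 and -3.68), a thaumatin family protein (TA15655_4097, -2.78 and -3.79) and STH-2. Some members were picked out after their values were seen: the basic form of PR-1 (TA15468_4097, -2.39 and -3.67), a basic chitinase (S44869, -1.43 and -2.03) and PR-4B (X58547, -1.08 and -1.26) were lower, while PR-4A (X58546, 2.79 and 1.90), PR-R (X12739, 2.53 and 1.17) and basic chitinase III (Z11564, 1.65 and 1.46) were higher, as was PR-1B above. Also picked out in this way, PR-Q (M29868, 0.89 and -0.46), acidic chitinase PR-P (X51426, 0.70 and -0.13) and acidic chitinase III (Z11563, 0.21 and 0.52) were not called at either time. The WRKY list had 9 higher and 6 lower of 25 members at 9 h, and 9 higher and 7 lower of 25 at 24 h. Its medians were -0.49 and -0.66 (percentiles 0.16 and 0.05) while its means were 0.57 and 0.01, the means being drawn up by WRKY4 and its neighbours. NtWRKY1 (AB022693, -1.32 ± 0.31 and -2.65 ± 0.36), NtWRKY-6 (AB063573, -1.67 and -1.67) and EH620388 (-1.61 and -2.14) were lower, and another WRKY-type probe (BP530025) was at least 15.6-fold lower at 24 h. The 9 h percentile of this list moved inside the random range with normexp, quantile normalization or the stricter filter, and its 24 h median with normexp (-0.01, percentile 49.8).

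Photosynthesis transcripts were higher in suppressed leaves. At 9 h, 30 of 80 members were higher and 2 lower (median 0.61), and at 24 h, 48 of 84 were higher and 2 lower (median 1.14), both at percentile 100. The 9 h median was 0.34 after median centring and 0.35 with normexp or the series value table, outside the random range in each. Plastocyanin (TA11762_4097) had 2.59 ± 0.24 and 2.83 ± 0.27, and the 23 kDa protein of photosystem II had 2.16 and 2.59 with a probe of the water-oxidizing complex (X64348) and 2.21 at both times with another (X55354). Oxygen-evolving enhancer protein 2-3 (EB434523) was 4.82-fold higher at 9 h and at least 8.73-fold higher at 24 h. The list of cytosolic ribosomal proteins also took in plastid ones through its search words, and its called members were nearly all of that kind: 10 of 208 were higher at 9 h, all of the plastid 30S or 50S type, and 9 of 206 were higher and 2 lower at 24 h (medians 0.00 and 0.10, percentiles 99.5 and 100). The plastid protein L3 (EB432942) had 1.74 and 1.72. With no filter the 9 h median of this list lay inside the random range (percentile 97.2), and after median centring it was -0.26, still at percentile 99.5. The senescence and proteolysis list had 4 higher and 1 lower of 28 at 9 h and 8 higher and 1 lower of 27 at 24 h (medians 0.37 and 0.51, percentiles 99.8 and 100), with a cysteine protease (EU429306, 1.02 and 1.85) among them. Its 9 h median was -0.12 with normexp and 0.19 with cyclic loess, inside the random range in both.

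At 9 h, the lists of redox, heat shock, cell wall, calcium and cell cycle genes had medians inside the random range, with members on both sides. Redox and detoxification had 10 higher and 14 lower of 75 at 9 h and 10 higher and 16 lower of 74 at 24 h (medians -0.04 and -0.25, percentiles 28.3 and 10.2), including NtPOX1 above and a probable glutathione S-transferase (TA14275_4097, -3.40 and -3.91). Heat shock and chaperones had 11 higher and 7 lower of 62, then 12 higher and 5 lower of 70 (medians 0.08 and 0.02, percentiles 93.6 and 93.3). Cell wall genes had 4 higher and 9 lower of 47, then 8 and 8 of 54 (medians 0.02 and -0.13, percentiles 59.7 and 45.7, with a mean of -0.22 at 9 h), and calcium signalling had 9 higher and 4 lower of 44, then 8 and 5 of 45 (medians -0.01 and -0.10, percentiles 56.6 and 36.0, with means of 0.10 and 0.02). Cell cycle and histone genes lay inside the random range at 9 h (median 0.02, percentile 61.5) and below it at 24 h, where 10 of 51 were lower and 6 higher (median -0.41, percentile 0.19). The 3 probes of RNA silencing enzymes were higher at 9 h, led by RNA-directed RNA polymerase (AJ011576, 2.44 ± 0.22), and 1 of them was higher at 24 h (1.31 ± 0.22).

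Markers of other cell types did not move together. The trichome and epidermis list had 2 higher and 0 lower of 9 members at each time (medians 0.18 and 0.17, percentiles 78.6 and 78.0), and T-phylloplanin (AB518673), a protein secreted by trichomes, had 0.18 and 0.14. The vascular list had 3 lower of 5 members at 9 h (median -1.14, percentile 0.33, but 2 members and no percentile with the stricter filter) and 2 lower of 4 at 24 h (median -1.71, too few for a percentile), with a fasciclin-like protein (BP532691) at least 8.07-fold lower at 9 h, and the sucrose transporter SUT1a (X82276), a gene of the phloem, at 0.29 and 0.27. The root and flower list, which took in some transcripts through the wording of their descriptions alone, had 2 of 17 members lower at 9 h and 3 of 17 at 24 h, with 0 higher (medians -0.11 and -0.13, percentiles 25.3 and 40.3). The control arrays held positions 1 and 2 of the slide and the suppressed arrays positions 3 and 4, and the genotype differences of 7 spike-in transcripts had an SD of at most 0.082.

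**Figure D3:**
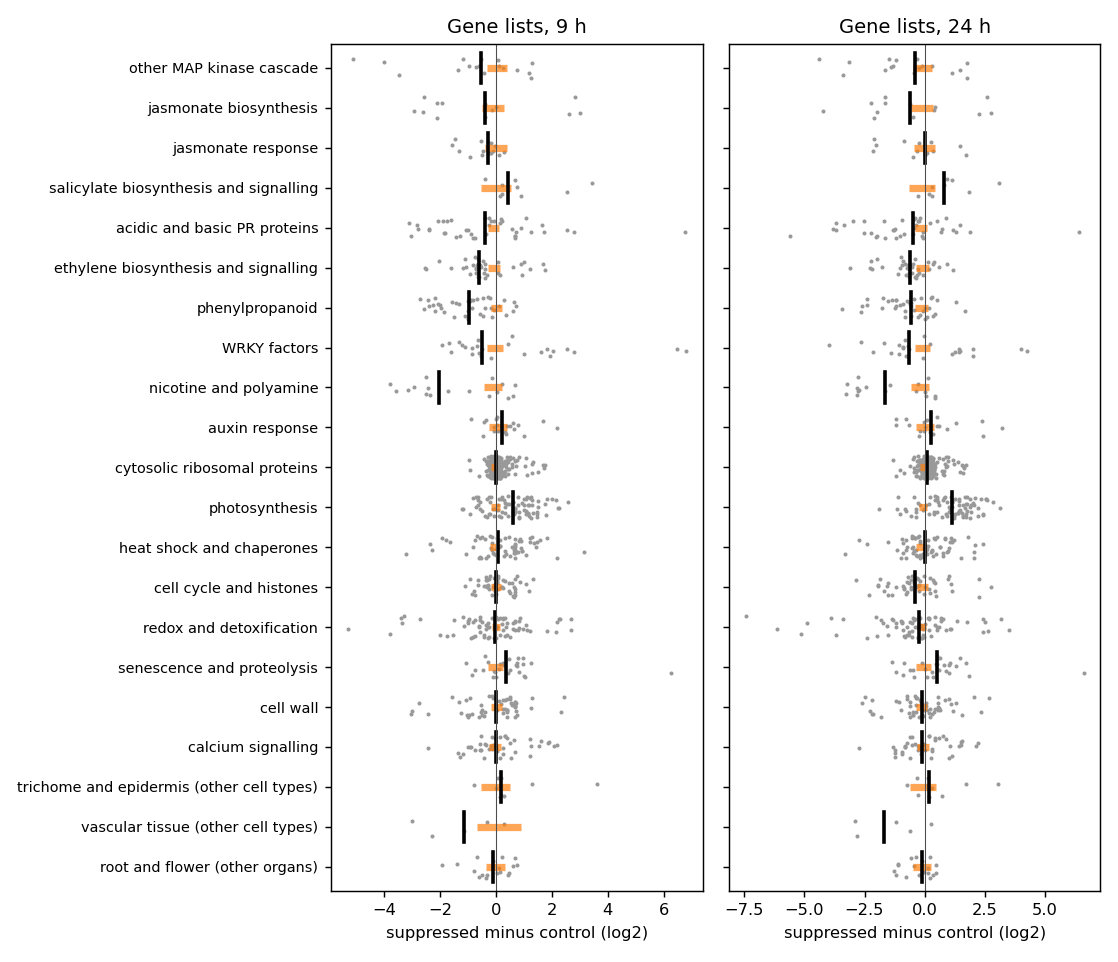
Log2 difference of suppressed minus control for the members of 21 gene lists at 9 h (left) and 24 h (right). Grey points are probes, black bars list medians, and orange bars the central 95% of the medians of 10000 random lists matched on signal, not drawn for lists with fewer than 5 members; the photosynthesis medians lie at 0.61 and 1.14 and those of nicotine and polyamine at -2.03 and -1.66.

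The change between 9 h and 24 h after wounding was compared within each genotype. No array held unwounded leaves or leaves without cycloheximide. An effect of wounding on these time differences therefore cannot be told apart from one of time of day or of cycloheximide. Across probes above background on all arrays these differences had a smaller SD than those between genotypes under each scaling run, at most 0.57 against at least 0.78, but by count of calls the order turned with normexp (3583 for time in control, 3545 for genotype at 24 h) and with no filter (15647 for time in control, 10050 for genotype at 9 h). In the control, MYB123 (TA14638_4097), a transcription factor, was 49.6-fold higher at 24 h (log2 difference 5.63 ± 0.26), heat shock protein 82 (X63195) at least 27.3-fold and galactinol synthase (TA17612_4097), an enzyme of raffinose sugar synthesis, at least 24.6-fold. The abscisic acid-inducible protein TAS14 (TA15607_4097) was 21.8-fold higher, early light inducible protein (TA12933_4097) 15.5-fold, the suberization-associated peroxidase (CV019292) 14.2-fold and histone H3 (DW003379) 11.6-fold. Lower at 24 h were the chloroplast protein of post-illumination chlorophyll fluorescence increase (TA16052_4097, -4.43 ± 0.26), the Drm3-like protein (TA17464_4097, -4.25 ± 0.28), EIG-I30 (TA16657_4097, -3.59), a pectin methylesterase inhibitor (TA16228_4097, -3.10), an auxin-repressed protein (TA11850_4097, -2.85) and a DnaJ-like protein (DV161197, -2.71). SLL2 protein (EH616620) was at least 17.6-fold lower.

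In suppressed leaves, MYB123 was at least 42.5-fold higher at 24 h, heat shock protein 82 16.7-fold and early light inducible protein 14.7-fold, while a pectin methylesterase inhibitor (TA14391_4097) was 62.5-fold lower, SLL2 protein 31.8-fold lower and THIC (TA20629_4097), an enzyme of thiamine synthesis, 15.5-fold lower. In the control, 1039 of 24162 probes were higher and 571 lower at 24 h, 6.7% in all, and in suppressed leaves 701 of 24818 were higher and 935 lower, 6.6%. The genotypes shared 361 higher and 272 lower probes, where independent lists would share 25.8 and 17.6, and 32 probes went in opposite directions against 45.3. Across the 20524 probes above background on all arrays the time differences had a Pearson r of 0.61 and a Spearman rho of 0.50, with an SD of 0.54 in control and 0.49 in suppressed leaves against 0.92 and 1.02 for the genotype differences at 9 h and 24 h. The balance of higher and lower calls in suppressed leaves depended on the scaling, with 42.8% higher as reported and 65.0% after median centring, which moved the median of all these probes to 0.21. With normexp, 607 probes were higher and 2976 lower in the control, the reverse of the order above, and 633 were higher and 230 lower in suppressed leaves.

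By list, heat shock and chaperones were higher at 24 h in both genotypes: 13 of 61 members were higher and 1 lower in control (median 0.54) and 17 of 71 higher and 3 lower in suppressed leaves (median 0.48), both at percentile 100. Between the suppressed arrays the spike-in transcripts shifted by a median of 0.41, near the size of this median and that of photosynthesis (0.39). The percentiles compare leaf probes alone. A heat shock cognate 70 kDa protein (TA13728_4097) had 2.98 ± 0.25 and 1.89. Auxin genes were on balance lower at 24 h (medians -0.47 and -0.44, both at percentile 0, with 3 of 19 and 1 of 19 called lower), as were senescence and proteolysis genes (medians -0.20 and -0.19, percentiles 0.21 and 0.27, 5 of 28 called lower in each), although median centring brought the latter to 0.01 and normexp the auxin list to 0.14 in suppressed leaves. Cell cycle and histone genes had 12 of 51 higher and 3 lower in control (median 0.21, percentile 99.5) and 3 higher and 1 lower of 49 in suppressed leaves (median 0.11, percentile 97.3, inside the random range). Photosynthesis had 19 of 84 members higher and 1 lower at 24 h in suppressed leaves (median 0.39, percentile 100) and 5 higher and 5 lower of 78 in control (median -0.09, percentile 2.41). Phenylpropanoid genes had a median of -0.21 in control (percentile 0, with a mean of 0.02) and 0.23 in suppressed leaves (percentile 100). Redox genes had medians of 0.32 (percentile 100) and 0.10 (percentile 97.9), the latter inside the random range with normexp, quantile normalization (percentile 92.9), no filter (-0.02, percentile 68.7) or random lists of named probes (percentile 89.4). Nicotine and polyamine genes had 0.41 in control (percentile 99.7) and 0.19 in suppressed leaves (percentile 95.7), jasmonate biosynthesis genes -0.10 (percentile 10.0, with a mean of 0.15) and 0.24 (percentile 97.9), and ethylene genes 0.03 (percentile 41.6) and -0.12 (percentile 0.26). The nicotine median in control was inside the random range with normexp (percentile 76.5) or no filter (90.8), the jasmonate biosynthesis median in suppressed leaves with normexp, cyclic loess or random lists of named probes, and the ethylene median in suppressed leaves with normexp, while median centring turned that last median to 0.08. With no filter the auxin median in suppressed leaves (percentile 3.81) was inside too, as was the photosynthesis median in control, which quantile normalization also brought inside (percentile 2.68). The ribosomal list had -0.04 in control (percentile 0.03, but 0.26 and inside the range with normexp) and 0.06 in suppressed leaves (percentile 39.1).

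Whether the genotype difference itself changed between 9 h and 24 h was described by the difference of differences, with 1 floor for all arrays. For some of these probes, among them the suberization-associated peroxidase, TAS14 and C-7 protein, it rests on arrays below that floor. It was 1 or more in size for 993 of 23946 probes, higher at 24 h for 410 and lower for 583. Highest among the named genes was the Drm3-like protein (TA17464_4097), at 2.55, which had time differences of -4.25 in control and -1.70 in suppressed leaves. Next were light harvesting chlorophyll a/b-binding protein (TA11623_4097, 2.25), which had a genotype difference of -0.48 at 9 h and 1.77 at 24 h, another chlorophyll a-b binding protein (TA12483_4097, 2.23), C-7 protein (TA18247_4097, 2.22) and polyphenol oxidase (TC122902, 2.20). Lowest were the suberization-associated peroxidase (CV019292, -3.83), the pectin methylesterase inhibitor (TA14391_4097, -3.41), TAS14 (TA15607_4097, -3.10), CYP71D49v1 (DQ350340, -3.07) and WRKY transcription factor 6 (CV016080, -2.55). The WRKY probe was 5.01-fold higher at 24 h than at 9 h in control and had -0.22 in suppressed leaves. This count depended on the scaling: 41.3% of these probes were higher as reported and 76.9% after median centring, and normexp gave 6804 probes.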

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

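These results met a rule for effects that point in opposite directions, in both genotypes or at both times, each beyond the 95% range of its spot error, at least 1 apart on the log2 scale and with at least 3 arrays well above background. Only the named genes were searched. The differences between them were not tested, since each group is 1 array. CYP71D49v1 (DQ350340) changed from 9 h to 24 h by 0.66 in control and by -2.41 in suppressed leaves, and CYP71D5v2 (EG649696) by 0.52 and -0.57. Luminal-binding protein 3 (TA19868_4097) changed by -0.49 in control and 1.12 in suppressed leaves. The phytosulfokine precursor (TA16652_4097) changed by 0.47 and -0.67, and the auxin-induced protein PCNT115 (BP192557) by -0.47 and 0.54. A light harvesting chlorophyll a/b-binding protein (TA11623_4097) changed by -1.59 in control and 0.66 in suppressed leaves, and its genotype difference was -0.48 at 9 h and 1.77 at 24 h.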

How the results depend on the processing

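The settings added after seeing the data were each array's own floor, the size limit on the additive fit, random lists from named probes and lists without the probes ordered by the floor. No paired analysis was possible because each group holds 1 array and so no replicate numbers to pair; the additive fit takes time as a block but pairs no plants. Counts of changed probes stayed within 1.5 times under the scalings, the stricter filter, the series value table and the spot error, and list counts did so under every setting. The exceptions follow, and unless stated the cause was not tested. With no filter, 10050 probes were called between genotypes at 9 h and 19676 at 24 h, 15647 between times in control and 6102 in suppressed leaves, and 18110 for the difference of differences. That setting adds probes that no array measured well above background. With normexp, the counts were 3583 in control and 863 in suppressed leaves for time, 1724 for the same genotype call at both times, 6804 for the difference of differences and 3802 for the additive fit. Each array's own floor gave 2081 for the difference of differences, the floors themselves differing between arrays, and asking the additive fit for a log2 of 1 gave 4624, a stricter rule by construction.

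The share of calls that were higher moved with the scaling. At 9 h it was 55.0% as reported, 43.3% with cyclic loess, 32.8% with median centring, 32.7% with the series value table and 18.4% with normexp. For the same call at both times it was 46.2% and, with median centring or the value table, 35.7%. For time in control it was 64.5%, and 54.1%, 53.8%, 53.7% and 16.9% in the order given for 9 h. In suppressed leaves it was 42.8%, with 56.1% for quantile normalization and 63.2%, 65.0%, 64.8% and 73.3% for the others. For the difference of differences it was 41.3%, and 61.7%, 76.9%, 77.1% and 91.4%. Median centring shifted the median difference of probes above background on all arrays to -0.29 at 9 h and to 0.21 for time in suppressed leaves.

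Of the values of named genes under other settings, 3647 stayed within the 95% range of the spot error, 201 left it and 10 changed sign, all 211 of them with normexp, where 349 stayed. Of the list medians, 767 stayed inside their bootstrap interval (for the 2 target kinases, the range of the 2), 87 left it and 10 were counted as changed in sign. That count does not hold the ribosomal list at 9 h, which went from 0.00 to -0.26 with median centring. With normexp, the genes that changed sign were heat shock protein 82 (X63195, -0.82), a calmodulin-binding heat-shock protein (S79243, -0.61), a lipid-transfer protein (BP531941, -0.48) and an Aux/IAA probe (TA12640_4097, -0.02) between genotypes at 9 h, PR-1B (EH624149, -0.50), XTH7 (TA11855_4097, -0.22), histone H2B (AJ632937, -0.16) and RNA-directed RNA polymerase (AJ011576, -0.05) for time in control, and NtWRKY1 (AB022693, 0.56) and the ethylene receptor homolog (BP526215, 0.36) for time in suppressed leaves. List medians changed sign with normexp for senescence at 9 h (-0.12), ribosomal proteins at 24 h (-0.05) and for time in control (0.26), and auxin for time in suppressed leaves (0.14). Median centring and the value table turned the time medians of ethylene (0.08) and senescence (0.01) in suppressed leaves, and no filter those of photosynthesis in control (0.02) and redox in suppressed leaves (-0.02). Of the lists outside the random range, 5 of 10 at 9 h, 8 of 11 at 24 h, 6 of 9 for time in control and 3 of 8 in suppressed leaves kept that place and the sign of their median under all 10 settings. The MAP kinase list, which holds the target SIPK, is among the 5 kept at 9 h. Some lists changed sign alone, such as the ribosomal list at 9 h, whose reported median was 0.00. Without the probes ordered by the floor, every list outside the range stayed outside, and 3 more fell outside: MAP kinase cascade at 24 h (-0.88) and, for time in suppressed leaves, cell cycle (0.13) and cell wall (0.15). Signal over background limits the rest: 18062 probes were well above background on no array.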

Other observations

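The lists in this part, and every test apart from those on spike-in transcripts and on cyclic loess, were chosen after the data were seen, and the interval limits used to judge the tests were added afterwards. Genes of the mevalonate pathway, which supplies the precursor of sesquiterpenes in the cytosol, were lower in suppressed leaves: 13 of 16 members of a list of this pathway and of cytosolic acetyl-CoA supply were lower at each time and 0 higher (medians -3.01 at 9 h and -2.78 at 24 h, both at percentile 0). They included HMG-CoA synthase (TA14823_4097, -3.82 and -3.62), HMG-CoA reductase (DW005032, -3.75 and -3.87), mevalonate kinase (BP526624, -3.88 and -3.60), isopentenyl diphosphate isomerase 2 (AB049816, -3.18 and -3.43), farnesyl pyrophosphate synthase (TA14923_4097, -3.08 and -2.65) and ATP:citrate lyase (TA13067_4097, -3.67 and -3.66). The cytosolic acetoacetyl-CoA thiolase AACT1 (AY748245) had -2.94 and -2.92, and its peroxisomal relative AACT2 (AY748246) -0.24 and -0.36. The other members not called were a protein farnesyltransferase subunit (EB435224, -0.21 and -0.39) and a farnesylated protein (CV019603, 0.97 ± 0.23 and at least 0.50). Neither is an enzyme of this pathway, and the list took them in through its search words. Of the CYP71D hydroxylases, some of which act on sesquiterpenes, 9 of 9 members were lower at 9 h and 9 of 10 at 24 h (medians -4.81 and -5.25).

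Plastid gene groups other than photosynthesis were on balance higher. Plastid ribosomal proteins had 10 of 30 members higher and 0 lower at 9 h, and 9 of 29 higher and 1 lower at 24 h (medians 0.60 and 0.81), while the 40S and 60S proteins of cytosolic ribosomes had medians of -0.05 and 0.06 over 119 and 118 members. The 40S and 60S median, though small, lay above the random range of -0.25 to 0.02 at 24 h (percentile 99.6) and inside its range at 9 h (percentile 90.3). Tetrapyrrole biosynthesis had 5 higher and 1 lower at each time, of 17 and 16 members (medians 0.61 and 0.79), with the Chl H subunit of magnesium chelatase (AF014052) at 1.34 and 1.42 and a glutamyl-tRNA reductase (TC158375) at -1.53 at 24 h. Proteasome subunits had medians of -0.03 and -0.01. Histones were higher at 24 h than at 9 h for 12 of 32 members in control (median 0.39) and 3 of 30 in suppressed leaves (median 0.17), and 9 of 32 were lower in suppressed leaves at 24 h (median -0.57).

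Chaperones of the endoplasmic reticulum (ER) were higher in suppressed leaves, 13 of 16 at 9 h and 15 of 16 at 24 h, with medians of 3.15 and 3.36. The exceptions at 9 h were 3 probes of protein disulfide isomerase (Y11209, -0.31; TA16299_4097, 0.19; DW002097, 0.85). Cross-hybridisation among the copies of the luminal binding protein was tested as the whole cause by the 10 probes of endoplasmin, calreticulin, calnexin and protein disulfide isomerase: their median was 2.05 at 9 h, and its lower bootstrap limits of 0.85 at 9 h and 1.31 at 24 h were above the 0.5 set for that cause, which argues against it, although the 9 h limit is below the 1 first asked of the median. A heat-shock response of all chaperones was argued against by the heat shock list, whose bootstrap interval reached no higher than 0.35. Several of the 10 probes are of the same protein, and the bootstrap counts them as separate. They bear on whether the rise was confined to the luminal binding proteins, and not on whether those probes read each other's transcripts. How much each luminal binding protein copy differed was not tested, and an effect of suppression and other differences between the plants both stay open.

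Photosynthesis probes were higher in suppressed leaves, with medians of 0.61 at 9 h and 1.14 at 24 h. A bias that depends on signal, which cyclic loess removes, was argued against as the whole cause: after it the medians were 0.60 (lower bootstrap limit 0.33) and 1.21 (limit 1.07), and random lists reached 0.14 and 0.20, while the share of higher calls at 9 h moved from 55.0% to 43.3%. At 9 h that limit is above the 0.3 set for such a bias but below the 0.5 first asked of the median, and median centring gave 0.34, so the size of the difference there is less certain. A larger share of mesophyll was left open by markers that were few: at 24 h the trichome and epidermis median was 0.17 (interval -0.33 to 1.71) and the vascular median -1.71 (interval -2.88 to 0.27). A genotype effect on plastid genes was not tested.

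Across the 20524 probes above background on all arrays, the difference between genotypes was larger than that between times, with SDs of 0.92 and 1.02 against 0.54 and 0.49. By count of calls, this order turned with normexp and with no filter. Differences between slide positions, in labelling or in scanning that act across the array would scatter the 7 spike-in transcripts too, but their genotype differences had an SD of at most 0.082 (1-sided upper 95% limit 0.158), which argues against these as the cause of the whole spread. Each spike-in value is a mean of 32 spots, so effects on single spots and differences in the leaf RNA itself were not tested. The spike-in transcripts also gave a median shift of 0.41 between the suppressed arrays at 24 h and 9 h, which scaling on the 75th percentile leaves in. With 1 array per genotype and time, differences between the plants or transformed lines other than the kinases cannot be told apart from an effect of suppression.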
